A study of Rattus norvegicus with 12 samples.

How the data were processed

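Gene expression was measured in epididymal white adipose tissue, the visceral fat pad that lies beside the epididymis, of 12 male Sprague-Dawley rats, with 1 Affymetrix Rat Gene 1.0 ST array per rat. The 4 fed rats, the 4 rats fasted until phase 2 and the 4 rats fasted until phase 3 were assigned to their groups from the sample titles, which also number the rats from 1 to 4 within a group. No technical replicates were run, per the labels' design text, so p-values measure the spread between rats. The extraction protocol in the labels speaks of liver samples, whereas the titles, the source names, the tissue labels and the other protocols all name white adipose tissue. The tissue was taken as adipose, and a list of hepatocyte genes was measured as a check.

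The deposited values were log2 expression levels per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises the probes of a probe set on a log2 scale. The same notes name GCOS and Affymetrix Expression Console 1.1. The library version and the RMA settings were not given in the sources used here. Detection calls, scan dates and array batches were not used here, so no batch could be tested. The number of arrays limits the precision, and the median of all probe sets lay between 6.026 and 6.1319 on every array.

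The value table held 29215 probe sets. The platform annotation gave 1 gene for 15310 of them, several genes for 323 and none for 13582, and no gene was named from the last 2 kinds. For the 526 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene, which left 14506 genes to be tested. Of these, 14481 matched a RefSeq gene of assembly GRCr8 by Entrez number, and 0 symbols needed updating. Coordinates were not used. Among the named genes with more than 1 probe set, Psmd8, Map1lc3b, Cs and Psma6 had probe sets that differed in whether they passed the test, and none had probe sets that passed in opposite directions.

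The comparisons were phase 2 against fed, phase 3 against fed and phase 3 against phase 2. All 12 arrays entered 1 linear model with a mean per group and no covariates, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that the groups shared their estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 14506 genes, and a gene was called at an adjusted p below 0.05. Changes are differences of group means in log2 units with the standard error (SE) of the model, and group levels are means with the standard deviation (SD) over 4 rats. The replicate numbers of the titles did not enter the main model. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the plots.

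Before the data were examined, 41 gene lists were written down, 26 for functions and 15 for cell types that an adipose sample could hold. Of their 760 entries, 686 were measured. Another 6 lay only on probe sets of several genes and were left out, among them Srebf1, Acaa1a, Dlst, Psma3 and Ciart. The function lists covered de novo lipogenesis, triglyceride synthesis and glyceroneogenesis, lipolysis and lipid droplets, fatty acid uptake and binding, mitochondrial fatty acid oxidation, fasting-induced PPAR targets and ketogenesis, cholesterol synthesis, glycolysis and pyruvate use, the citric acid cycle, the respiratory chain, insulin signalling, FOXO and atrophy-associated genes, proteasome subunits, autophagy and lysosome, glucocorticoid-induced genes, endoplasmic reticulum (ER) stress and the amino acid response, amino acid catabolism, extracellular matrix, adipokines, adipogenic transcription factors, cell cycle, inflammatory mediators, interferon response, antioxidant and detoxification genes, the circadian clock and thermogenic adipocyte genes. The cell type lists held markers of adipocytes, macrophages, neutrophils, T and NK cells, B cells, mast cells, endothelium, fibroblasts and progenitors, mesothelium, smooth muscle, skeletal muscle, epididymis and testis, hepatocytes, erythroid cells, and Schwann cells and nerve.

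Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, again with a correlation estimated from the arrays, and with fry, whose directional p asks whether a list's genes move on balance one way. List p-values were adjusted over the 41 lists. For each list the members past the threshold were counted among all genes tested and also adjusted over the list alone.

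Named genes followed a rule also fixed before the data were examined. In each comparison the rule took the 6 largest rises and the 6 largest falls among called genes whose values in the 4 rats of each group did not overlap, up to 3 members with the smallest adjusted p from each list described, and always Lep, Adipoq, Pck1, Pdk4, Fasn, Pnpla2, Lipe, Lpl, Fbxo32 and Cpt1a. Genes named outside the rule are said to be so.

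The steps were tested on simulated data with the real gene means and spreads, for phase 2 against fed over 14506 genes. The model recovered 70.15% of 67 genes changed 1.5-fold, 92.54% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 7.41% of its calls were unchanged genes. Only these few genes were changed, and the noise was drawn independently for each gene. The real comparisons called 25.2% to 45.4% of genes, so these shares need not carry over to them.

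The alternatives were a fit of only the groups compared, the replicate number as a block, quantile normalisation of the deposited values, centring of each array on the median of the tested genes, leaving out the dimmest 40% of genes, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, a test of every probe set, a minimum change of 1 log2 unit, leaving out each rat in turn and, for the lists, an estimated correlation and fry. Cyclic loess normalisation and comparison of each list with 10000 random lists matched on mean level were added after the data had been seen. Ranges and counts given over the alternatives, or over all of them, cover for a list the 18 runs of camera at its preset correlation. They leave out the estimated correlation and fry. For a named gene they leave out the test of every probe set and the minimum change. Overlaps between comparisons that share a group were set beside 50 simulations of unchanged groups, beside independent lists, and beside splits of the shared group into pairs of rats.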

Results

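Expression was measured in the epididymal fat pad of 12 male rats that were fed, or fasted until phase 2 or phase 3, with 4 rats in each group. In phase 2 of a long fast the body lives mainly on its fat stores and spares protein, and in phase 3 the breakdown of body protein rises. The data hold 1 array per rat and 14506 named genes that could be tested. The arrays were comparable in level, with upper quartiles between 7.8287 and 8.0239 on the log2 scale.

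The 3 groups separated along the first principal component, which held 63.1% of the variance. Fed rats lay between -40.83 and -34.85 on it, phase 2 rats between -3.634 and 1.613 and phase 3 rats between 37.1 and 42.67. The second component, with 14% of the variance, set phase 2 rats apart, at -24.74 to -15.95. On the third, with 6.57%, phase 3 rat 2 (22.65) and phase 3 rat 3 (-24.88) stood apart from the other phase 3 rats.

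**Figure D1:**
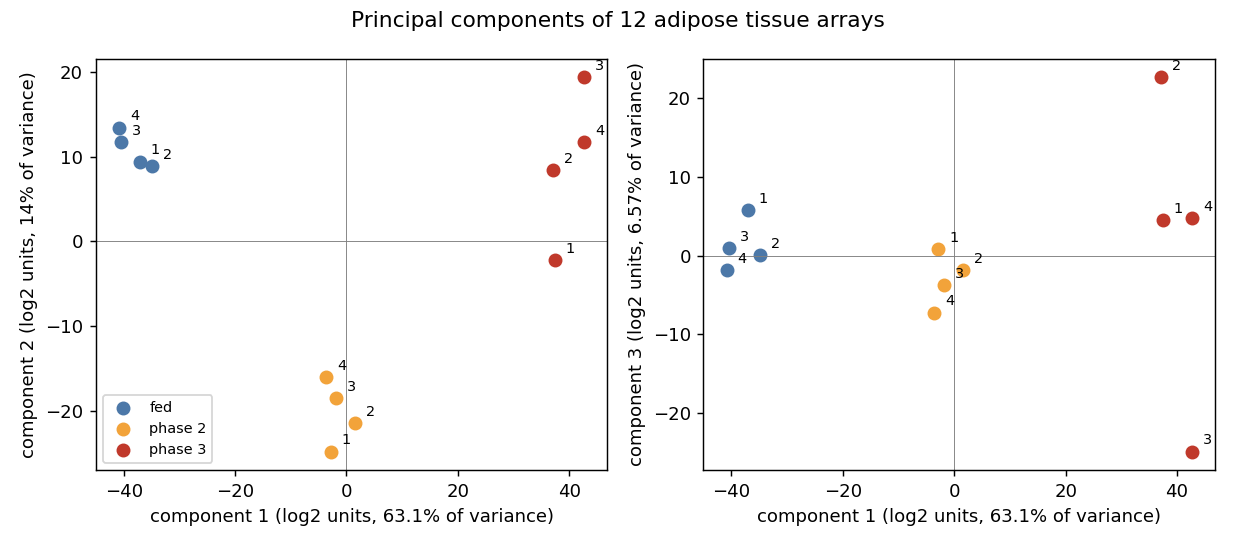
Scores of the 12 arrays on the principal components of the log2 expression levels, with component 1 on the horizontal axis of both panels and component 2 (left) or 3 (right) on the vertical axis, where each point is 1 rat, coloured by group and numbered within its group. Component 1 runs from -40.83 in fed rat 4 to 42.67 in phase 3 rat 4, with all phase 2 rats between -3.634 and 1.613.

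The first comparison asked what differed in the fat pad of rats in phase 2 from that of fed rats. Genes of fat synthesis were lower. Pnpla3, a lipase-like protein of lipid droplets, fell by 5.27 ± 0.0865 (SE) on the log2 scale, which was 38.5-fold. Scd, the stearoyl-CoA desaturase, fell by 5.20 ± 0.217 and Fasn, the fatty acid synthase, by 4.48 ± 0.162. Lep, which encodes leptin, fell by 4.12 ± 0.308. Cyp2e1, a cytochrome P450 that oxidises ethanol and acetone, rose from a log2 level of 5.05 ± 0.339 to 11.4 ± 0.31 (SD, n = 4), which was 81.4-fold. Detection calls were not used, so its fed level was not shown to lie above background and the fold is not exact. Over all genes 1401 were higher and 2248 lower in phase 2, 25.2% of those tested (limma, Benjamini-Hochberg adjusted), and 167 and 265 of them differed at least 2-fold. Values of the 4 rats in each group did not overlap for 31% of all genes, where chance gives 2.86%.

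The other large rises in phase 2 were Gulo, the enzyme of the last step of vitamin C synthesis (4.19 ± 0.273), the calmodulin-like Calml3 (3.94 ± 0.311), Slc27a2, a fatty acid transport protein and acyl-CoA synthetase (3.54 ± 0.394), the matrix glycoprotein gene Thbs1 (3.37 ± 0.206) and Pdk4, the kinase that switches off pyruvate dehydrogenase (3.05 ± 0.173). The other large falls were Oxtr, the oxytocin receptor (-5.27 ± 0.114), and the imprinted gene Mest (-3.44 ± 0.215). Each of these had an adjusted p of 2.23e-05 or less in limma's test.

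Of the 15 measured genes of de novo lipogenesis, 14 fell and 1 rose in phase 2 (camera adjusted p = 1.26e-13, and adjusted p = 0.041 with an estimated correlation). The gene that rose was Acacb, an acetyl-CoA carboxylase that is known to restrain fatty acid oxidation. It changed by 3.04 ± 0.17 and is named for this comparison after its value was seen. All 20 genes of cholesterol synthesis fell, with a median of -1.04 (camera adjusted p = 2.79e-20, and adjusted p = 0.0181 with an estimated correlation). Among them were Sqle, the squalene epoxidase (-2.10), Idi1 (-2.12) and Nsdhl (-1.87).

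Triglyceride handling was mixed in phase 2. Of 12 genes of triglyceride synthesis and glyceroneogenesis, 4 fell and 2 rose. Dgat2, which adds the last fatty acid to a triglyceride, fell by 2.05 and the acyltransferase Gpam by 0.98. Pck1, the cytosolic enzyme of glyceroneogenesis, rose by 1.03 ± 0.309 (adjusted p = 0.0243, and between 0.000456 and 0.0746 over the alternatives). Its call ended without fed rat 2 or 4 or phase 2 rat 1 or 2, at adjusted p of 0.0746, 0.0533, 0.0586 and 0.0601, and with an intensity trend and robust prior, at 0.0521. Of 14 genes of lipolysis and the lipid droplet, 4 rose and 2 fell, and 5 and 3 did so adjusted over the list alone. Pnpla2, the adipose triglyceride lipase, rose by 0.53 ± 0.0897 and G0s2, its inhibitor, fell by 0.85. Lipe, the hormone-sensitive lipase, differed by 0.13 ± 0.132 (adjusted p = 0.543), Lpl, the lipoprotein lipase, by 0.03 ± 0.0777 (adjusted p = 0.833) and Adipoq, which encodes adiponectin, by -0.06 ± 0.169 (adjusted p = 0.853). None of these 3 passed the test.

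Some genes of fatty acid uptake and use rose, but none of the 3 lists passed camera at its preset correlation. With an estimated correlation the uptake list and the PPAR targets each had a camera adjusted p of 0.442. With fry, which does not compare a list with other genes, both passed as higher (adjusted p of 0.00471 and 0.0056). Of 11 uptake genes 4 rose, among them Angptl4 (1.06), an inhibitor of lipoprotein lipase, Gpihbp1 (0.88), its anchor on the capillary wall, and Slc27a1 (1.06), and 1 fell (camera adjusted p = 0.0575, and between 0.0335 and 0.0859 over the alternatives). Of 15 fasting-induced PPAR targets 6 rose and 1 fell (camera adjusted p = 0.0905, and between 0.0298 and 0.182 over the alternatives), with Pdk4 and the peroxisomal Ehhadh (1.84) higher and Bdh1, a ketone body enzyme, lower (-0.96). Of 19 genes of mitochondrial fatty acid oxidation 4 rose and 2 fell (camera adjusted p = 0.179). Ech1 rose by 1.20, Acadl by 0.57 and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, by 0.76 ± 0.103.

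Of 21 genes of glycolysis and pyruvate use, 18 fell and 2 rose (camera adjusted p = 8.01e-09, and adjusted p = 0.117 with an estimated correlation), with Ldha, the lactate dehydrogenase, at -1.15 and the pyruvate dehydrogenase subunits Dlat at -1.38 and Pdhb at -1.41. In the citric acid cycle 9 of 16 genes fell and none rose (camera adjusted p = 0.00132, and adjusted p = 0.466 with an estimated correlation), led by Mdh2 (-0.62) and pyruvate carboxylase, Pc (-1.24). In the respiratory chain 19 of 25 fell and none rose (camera adjusted p = 1.49e-08, and adjusted p = 0.442 with an estimated correlation), among them Cox5b (-0.67) and Uqcrc1 (-0.58). Slc2a4, the insulin-dependent glucose transporter, fell by 1.88, while the insulin receptor gene Insr rose by 1.12. Of the 18 genes of insulin signalling, 7 rose and 6 fell.

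FOXO targets and atrophy-associated genes rose, with 11 of 18 higher and 1 lower in phase 2 (camera adjusted p = 3.3e-07, and adjusted p = 0.041 with an estimated correlation). Trim63, a ubiquitin ligase known from wasting muscle, rose by 2.31, the autophagy gene Gabarapl1 by 1.26, Bnip3 by 1.25 and Fbxo32, the other ubiquitin ligase of muscle atrophy, by 0.92 ± 0.12. Of 19 glucocorticoid-induced genes 10 rose and none fell, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00101, and adjusted p = 0.442 with an estimated correlation). Klf15 rose by 1.24 and Sgk1 by 1.26. The mean over the glucocorticoid list overlapped between the groups, with fed rat 1 at 0.4029 and phase 2 rat 3 at 0.1953 relative to the fed mean. Proteasome subunits were lower, with 22 of 32 down and none up (camera adjusted p = 4.47e-08, and adjusted p = 0.401 with an estimated correlation), such as Psmb6 (-0.56) and Psmd8 (-1.03, and -0.63 as the mean of its probe sets, of which the dimmer did not pass). In the list of ER stress and the amino acid response 11 of 21 genes fell and 1 rose (camera adjusted p = 0.00336, and adjusted p = 0.442 with an estimated correlation). Those that led it, Calr (-0.74), Dnajc3 (-0.70) and Pdia6 (-0.84), are chaperones of the ER lumen. Of 30 genes of autophagy and lysosome 7 rose and 6 fell, and of 22 genes of amino acid catabolism 6 rose and 5 fell, with the aminotransferases Gpt2 at 2.18 and Gpt at -1.75.

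Of 31 cell cycle genes 29 fell and none rose in phase 2, with a median of -1.15 (camera adjusted p = 1.67e-16, and adjusted p = 0.401 with an estimated correlation), among them Ect2 (-1.72), Nusap1 (-1.74) and Rrm2 (-2.01). Extracellular matrix genes fell in 11 of 22 cases and rose in 1 (camera adjusted p = 0.000224, and adjusted p = 0.442 with an estimated correlation), with the collagen chaperone Serpinh1 at -1.16, Loxl2 at -1.59 and fibrillin, Fbn1, at -1.17. Markers of fibroblasts and progenitors moved with them, 6 of 13 down, such as Thy1 (-1.59) and Cd34 (-1.28), and 2 up (camera adjusted p = 0.0346, and adjusted p = 0.442 with an estimated correlation). Mesothelial markers fell in 6 of 11 cases (camera adjusted p = 0.00398, and adjusted p = 0.442 with an estimated correlation), with Krt8 at -1.09. Smooth muscle markers rose in all 10 cases, by a median of 1.19 (camera adjusted p = 1.52e-07, and adjusted p = 0.401 with an estimated correlation), led by Myh11 (1.71), Tagln (1.25) and Lmod1 (1.29). Endothelial markers rose in 10 of 14 cases and fell in 1 (camera adjusted p = 5.81e-06, and adjusted p = 0.237 with an estimated correlation), with Pecam1 at 0.69 and Tek at 0.80.

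Among adipocyte markers 2 of 13 rose, Pnpla2 and Acvr1c (1.11), an activin-type receptor, and 1 fell, Lep. Of 13 adipokines 5 fell and 3 rose, with chemerin, Rarres2, at -1.54 and Nampt at 1.07. Of 17 adipogenic transcription factors 5 rose and 2 fell. Blood cell markers showed few calls. Of T and NK cell markers 1 of 17 rose (camera adjusted p = 0.0512, and between 0.0353 and 0.177 over the alternatives, of which 10 passed). Of B cell markers 1 of 8 fell, of mast cell markers 2 of 10 rose and of erythroid markers 1 of 6 rose. The mast cell call of Tpsb2 ended in 10 alternatives, among them without fed rat 2 or 4, phase 2 rat 2, 3 or 4 or phase 3 rat 2 or 4 (adjusted p between 0.0517 and 0.149), and the erythroid call of Hba-a3 ended in 5, among them without fed rat 3 or 4 or phase 2 rat 2 or 3 (between 0.0536 and 0.0887). Of the macrophage markers 2 of 19 rose, Gpnmb (1.43) and Cd163 (0.78), and 2 fell. The neutrophil receptor Cxcr2 fell by 1.89 and no other of 11 neutrophil markers passed. Interferon response genes fell in 3 of 26 cases (camera adjusted p = 0.034, and adjusted p = 0.762 with an estimated correlation), all members of the antigen-processing or interferon signalling machinery such as Psmb8 (-0.66) and Stat2 (-0.56). The call of Psmb10 ended in 7 alternatives, among them without fed rat 1, 3 or 4 or phase 2 rat 1 or 2 (adjusted p between 0.0524 and 0.0988). Neither skeletal muscle markers (0 of 11) nor epididymis and testis markers (0 of 13) held a called gene in limma's test, and of 14 hepatocyte markers only Apoc3 was called, at -1.33. Of the remaining lists, inflammatory mediators held 1 rise and 1 fall among 25 genes, antioxidant genes 2 and 6 among 23, circadian clock genes 3 and 1 among 15, thermogenic genes 2 and 0 among 9, and Schwann cell and nerve markers 1 and 2 among 7. The thermogenic call of Ppargc1a ended in 8 alternatives, among them without fed rat 1, 3 or 4 or phase 2 rat 1, 2 or 3 (adjusted p between 0.053 and 0.109). The call of Tlr2, the fall among inflammatory mediators, ended without phase 2 rat 2 (adjusted p = 0.0545). That of the clock gene Npas2, a rise, ended without fed rat 4 or phase 2 rat 2 or 3 (adjusted p between 0.0516 and 0.0572). The median and the test differed in sign for 3 of the 41 lists, none of them called.

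With an estimated correlation between genes, 3 of the 16 lists called in phase 2 against fed kept their call, namely de novo lipogenesis, cholesterol synthesis and the FOXO and atrophy-associated genes. The call of the interferon list ended with cyclic loess normalisation, without the dimmest 40% of genes and without fed rat 2 or 3 or phase 2 rat 1 or 3 (adjusted p between 0.0562 and 0.159 there, and between 0.000345 and 0.159 over all alternatives), and that of the fibroblast list with quantile normalisation, without the dimmest genes and without fed rat 1 or 2 or phase 2 rat 2 or 3 (between 0.0504 and 0.151 there, and between 0.0143 and 0.151 over all).

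**Figure D2:**
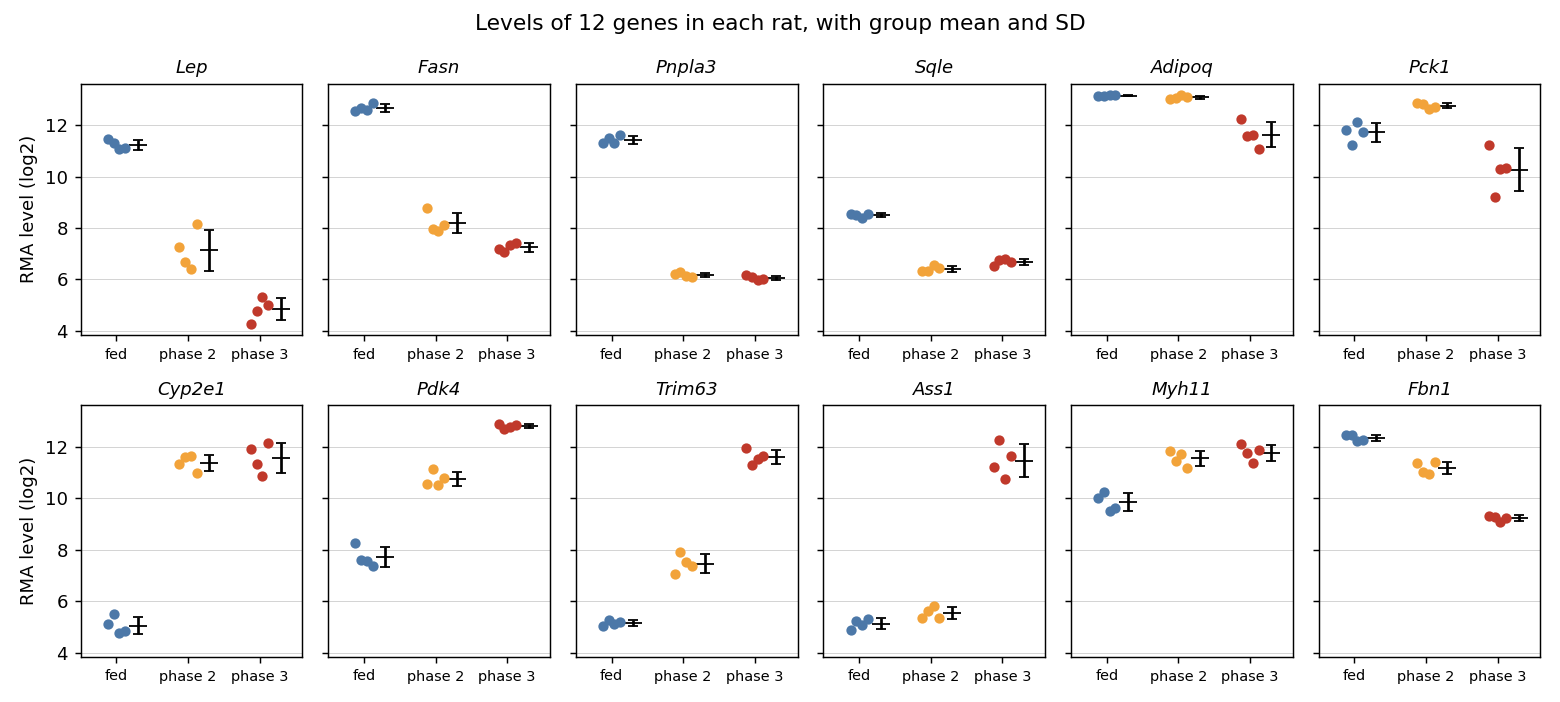
Log2 expression levels (vertical axis) of 12 genes in fed, phase 2 and phase 3 rats (horizontal axis), where each point is 1 rat and the bar beside it is the group mean with its SD (n = 4). Lep falls from 11.2 to 7.13 to 4.84, Cyp2e1 rises from 5.05 to 11.4 and stays at 11.6, and Ass1 rises only in phase 3, from 5.13 and 5.53 to 11.5.

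The second comparison set phase 3 against fed rats. Sdr16c6, a short-chain dehydrogenase, rose to a log2 level of 11.3 ± 0.243 (SD, n = 4). Its fed level of 3.71 was near the mean of 3.59 of the olfactory receptor genes, which are taken here as mostly silent in fat. The change of Sdr16c6, 7.54 ± 0.539, was therefore measured from near background, and no exact fold is given. Trim63 rose by 6.45 ± 0.163, Cyp2e1 by 6.53 ± 0.249 and Ass1, the argininosuccinate synthase of arginine and urea synthesis, by 6.34 ± 0.244. Lep fell by 6.40 ± 0.308, which was 84.47-fold, but its phase 3 level was not shown to lie above background, so the fold is not exact. Adipoq, unlike in phase 2, was lower, by 1.52 ± 0.169. In all, 3066 genes were higher and 3523 lower, 45.4% of those tested (limma, Benjamini-Hochberg adjusted), of which 472 and 907 differed at least 2-fold. The values of the rats did not overlap for 41.9% of genes, against 2.86% by chance.

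The split between higher and lower genes depended on the scaling. The arrays' medians over the tested genes averaged 6.975 in fed, 6.91 in phase 2 and 6.82 in phase 3 rats, so phase 3 arrays lay at -0.155 relative to fed arrays. As deposited, 46.5% of the genes called in phase 3 against fed were higher, and with each array centred on that median 69.6%, or 6115 higher and 2670 lower. The same centring moved the share from 38.4% to 53% in phase 2 against fed and from 45.8% to 64.9% in phase 3 against phase 2.

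Other large rises in phase 3 were Pdk4 (5.11 ± 0.173) and Prg4, which encodes lubricin (4.59 ± 0.295). Large falls were those of the imprinted genes Nnat (-5.90 ± 0.275) and Mest (-5.49 ± 0.215), Fasn (-5.43 ± 0.162), the succinate receptor gene Sucnr1 (-5.39 ± 0.141) and Pnpla3 (-5.38 ± 0.0865).

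De novo lipogenesis genes fell in 13 of 15 cases and rose in 1, Acacb, by 4.10 (camera adjusted p = 3.13e-08, and adjusted p = 0.183 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 20 cases (camera adjusted p = 8.41e-10, and adjusted p = 0.108 with an estimated correlation), with Idi1 at -2.25 and Sqle at -1.83. Triglyceride synthesis genes fell in 10 of 12 cases and rose in 2 (camera adjusted p = 0.000437, and adjusted p = 0.232 with an estimated correlation), with the glycerol channel Aqp7 at -3.31 and the acyltransferases Gpam at -2.02 and Gpat3 at -1.71. Pck1, higher in phase 2, was lower than in fed rats, by 1.46 ± 0.309.

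Lipolysis and lipid droplet genes fell in 7 of 14 cases and rose in 1 (camera adjusted p = 0.0261, and adjusted p = 0.438 with an estimated correlation). G0s2 fell by 3.62, the droplet protein gene Cidec by 1.63 and Lipe by 0.92 ± 0.132, while Plin2, which coats small droplets, rose by 1.03. Pnpla2 differed by 0.04 ± 0.0897 (adjusted p = 0.744). Lpl fell by 0.22 ± 0.0777 (adjusted p = 0.0352, and between 0.00591 and 0.506 over the alternatives), a call that ended in 10 alternatives, among them centred arrays (0.506), a fit of only these groups (0.066) and when any 1 fed rat or phase 3 rat 2, 3 or 4 was left out, at adjusted p between 0.0508 and 0.0955. Fatty acid oxidation genes fell in 8 of 19 cases and rose in 3, but with arrays centred on their medians 5 rose and 5 fell. Acaa2 was at -1.14 and Acadm at -0.81, while Cpt1a rose by 0.86 ± 0.103. Of the fatty acid uptake genes 5 of 11 fell and 3 rose (3 and 3 with centred arrays), with the acyl-CoA synthetase Acsl1 at -1.75. Of the PPAR targets 6 rose and 2 fell.

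Glycolysis genes fell in 16 of 21 cases and rose in 2 (camera adjusted p = 4.94e-07, and adjusted p = 0.183 with an estimated correlation), with Ldha at -2.19 and Tpi1 at -1.62. Citric acid cycle genes fell in 13 of 16 and rose in 1 (camera adjusted p = 0.000214, and adjusted p = 0.449 with an estimated correlation), with Pc at -3.12 and the citrate synthase Cs at -1.12. For Cs the mean of its probe sets gave -0.58, as its dimmer probe set did not pass. Respiratory chain genes fell in 20 of 25 (camera adjusted p = 4.27e-09, and adjusted p = 0.337 with an estimated correlation), with Ndufs3 at -1.32. In insulin signalling 7 rose and 6 fell of 18, with Igfbp3, which binds insulin-like growth factors, at 2.73, Igf1 at -1.66 and the kinase gene Akt2 at -1.58.

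FOXO and atrophy-associated genes rose in 15 of 18 cases and none fell (camera adjusted p = 4.09e-09, and adjusted p = 0.0337 with an estimated correlation), with Trim63, Gabarapl1 (2.29), Fbxo30 (1.53) and Fbxo32 (2.14 ± 0.12). Glucocorticoid-induced genes rose in 15 of 19 cases and fell in 1 (camera adjusted p = 1.46e-06, and adjusted p = 0.296 with an estimated correlation), led by the metallothionein gene Mt1 (4.52), Klf15 (2.39) and Cebpd (1.504). Circadian clock genes rose in 10 of 15 and fell in 2 (camera adjusted p = 0.00335, and adjusted p = 0.199 with an estimated correlation), among them Tef (1.30), Nr1d2 (0.97) and Npas2 (0.98). Autophagy and lysosome genes rose in 14 of 30 and fell in 7 (camera adjusted p = 0.0812, and between 0.0146 and 0.125 over the alternatives), with Map1lc3b at 1.30 and the protease gene Ctsl at 1.51. The autophagy list passed with fry (adjusted p = 3.94e-05) but not with an estimated correlation (camera adjusted p = 0.585). Proteasome subunits fell in 11 of 32 cases and rose in 5, a majority that turned with centred arrays, where 7 fell and 10 rose. In ER stress and the amino acid response 13 of 21 fell and 6 rose, with Calr at -1.46 and the asparagine synthetase gene Asns at -1.56. Amino acid catabolism genes fell in 7 of 22 cases and rose in 6 (7 and 9 with centred arrays), with Gpt at -3.15 and the glutamate dehydrogenase Glud1 at 1.33. Antioxidant genes fell in 9 of 23 cases and rose in 7 (9 and 10 with centred arrays), with extracellular superoxide dismutase, Sod3, at -2.52 and the glutathione transferase Gstm1 at 1.59.

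Adipocyte markers fell in 12 of 13 cases, by a median of 1.63 over the list (camera adjusted p = 2.34e-06, and adjusted p = 0.327 with an estimated correlation), and 11 of the 13 also stood in another list. Adipokines fell in 10 of 13 and rose in 2 (camera adjusted p = 0.00194, and adjusted p = 0.183 with an estimated correlation), with Nampt at 2.29. Of adipogenic transcription factors 5 of 17 rose and 5 fell. Matrix genes fell in 18 of 22 cases and rose in 1 (camera adjusted p = 8.41e-10, and adjusted p = 0.199 with an estimated correlation), with Loxl2 at -3.50, Fbn1 at -3.12 and Serpinh1 at -2.50. Fibroblast markers fell beside them in 10 of 13 and rose in 2 (camera adjusted p = 0.000125, and adjusted p = 0.232 with an estimated correlation), with Thy1 at -2.38 and Dpp4 at -2.13. Mesothelial markers fell in 7 of 11 (camera adjusted p = 0.00107, and adjusted p = 0.327 with an estimated correlation), with mesothelin, Msln, at -1.97. Cell cycle genes fell in 29 of 31 and rose in 2 (camera adjusted p = 6.47e-10, and adjusted p = 0.37 with an estimated correlation), with Bub1 at -1.87, Ect2 at -2.31 and the replication helicase Mcm7 at 1.59. Smooth muscle markers rose in 9 of 10 (camera adjusted p = 0.00107, and adjusted p = 0.509 with an estimated correlation), with Myh11 at 1.93 and Myocd, the regulator of the smooth muscle programme, at 1.51. Endothelial markers rose in 7 of 14 and fell in 2 (camera adjusted p = 0.0385, and adjusted p = 0.509 with an estimated correlation).

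Immune genes went both ways. Inflammatory mediators rose in 9 of 25 cases and fell in 6, with the acute-phase gene Hp, haptoglobin, at 1.79 and the NF-kappa-B inhibitor Nfkbia at 1.94. Orm1, another acute-phase gene, also rose, from a fed level of 3.65 near that of the olfactory receptor genes, so the size of its change is not exact. Interferon response genes fell in 7 of 26 and rose in 1 (camera adjusted p = 0.0385, and adjusted p = 0.789 with an estimated correlation), with Psmb8 at -1.28. This call ended in 8 alternatives, among them leaving out fed rat 2 or 3 or phase 3 rat 1, 3 or 4 (adjusted p between 0.0596 and 0.193), while without phase 3 rat 2, which had the highest mean over the list in its group, the adjusted p was 5.79e-06. Macrophage markers fell in 7 of 19 and rose in 5, a majority that turned with centred arrays (4 and 7) and with quantile normalisation (4 and 5), and Gpnmb was at 2.10. Of 11 neutrophil markers 3 rose and 1 fell, Cxcr2 (-3.69). T and NK cell markers fell in 4 of 17 cases (2, with 4 rising, in centred arrays), B cell markers fell in 2 of 8 and rose in 1 (1 and 1 in centred arrays) with Cd22 at -1.36, and 1 of 10 mast cell markers fell and 1 rose. Of 7 Schwann cell and nerve markers 4 fell and 2 rose, with S100b, which fat cells also express, at -2.98. Of 9 thermogenic genes 1 rose, Ppargc1a, by 0.75, and 1 fell. Of 6 erythroid markers 3 fell, of 13 epididymis and testis markers 3 rose, and of 14 hepatocyte markers 1 rose and 2 fell (5 and 2 with centred arrays, 0 and 2 with cyclic loess). Several of these calls ended when 1 rat was left out, namely that of Hbb without fed rat 1, 3 or 4 (adjusted p up to 0.0669), those of Rnase10 without fed rat 2, 3 or 4 or phase 3 rat 2, 3 or 4 (up to 0.114), those of Alb without fed rat 1, 3 or 4, phase 2 rat 1 or 4 or phase 3 rat 3 or 4 (up to 0.137) and those of Apoh without fed rat 1 or 3 (up to 0.0608). Of the B cell calls, Blk, the rise, ended in 14 alternatives (up to 0.157), among them without fed rat 1, 3 or 4, phase 2 rat 2, 3 or 4 or phase 3 rat 2, 3 or 4, and Ms4a1 ended without phase 3 rat 1 (0.053). The median and the test differed in sign for 2 of the 41 lists, neither of them called.

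With an estimated correlation only the FOXO and atrophy-associated list kept its call among the 19 called in phase 3 against fed. Leaving out the dimmest 40% of genes ended the calls of the cell cycle list (adjusted p = 0.0988, between 4.62e-13 and 0.0988 over the alternatives) and the lipolysis list (adjusted p = 0.165, between 0.00156 and 0.165), and the endothelial list lost its call with centred arrays and without fed rat 2 or 4 or phase 3 rat 1, 2 or 4 (adjusted p between 0.0504 and 0.0788 there, and between 0.0146 and 0.0788 over all).

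**Figure D3:**
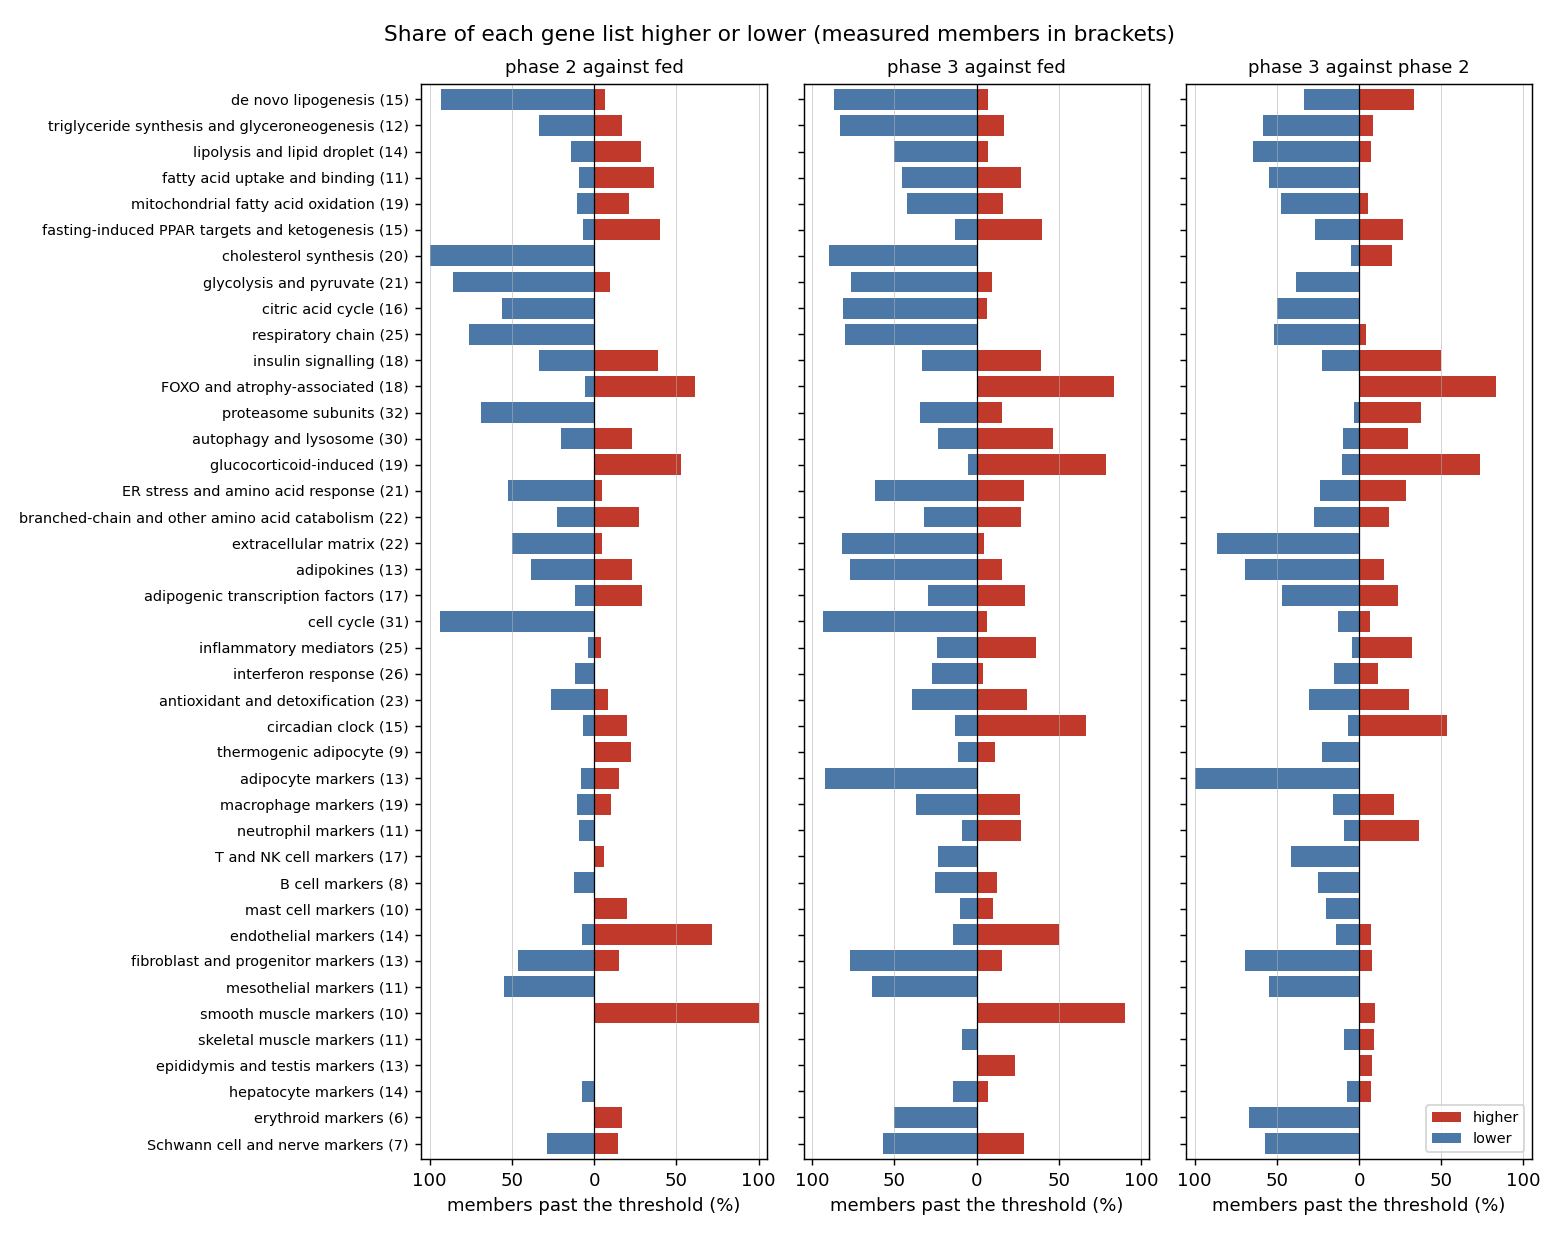
Share of the measured members of each of the 41 gene lists (rows, with the number of members in brackets) that were higher (red, to the right) or lower (blue, to the left) at an adjusted p below 0.05, in percent on the horizontal axis, in each of the 3 comparisons. Cholesterol synthesis is lower throughout in phase 2 against fed (20 of 20), smooth muscle higher (10 of 10), and adipocyte markers lower throughout in phase 3 against phase 2 (13 of 13), while the majority among proteasome subunits in phase 3 against fed (11 lower and 5 higher) turned when arrays were centred on their medians.

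The third comparison set phase 3 against phase 2, within the fasted rats. Ass1 rose by 5.94 ± 0.244 on the log2 scale, or 61.46-fold, from a level of 5.53 ± 0.23 in phase 2 rats, where the fed level was 5.13 ± 0.198 (SD, n = 4). The phase 2 level of Ass1 was not shown to lie above background, so the fold is not exact. Trim63 rose by 4.14 ± 0.163. Sdr16c6 rose by 5.32 ± 0.539 from levels in phase 2 rats that ranged from 4.3957 to 7.94, and by 5.986 without phase 2 rat 3. Slc36a2, an amino acid transporter of the adipocyte surface, fell by 3.89 ± 0.258 and Sucnr1 by 3.81 ± 0.141. All 13 adipocyte markers were lower in phase 3. In total 1853 genes were higher and 2193 lower, 27.9% of those tested (limma, Benjamini-Hochberg adjusted), of which 210 and 312 differed at least 2-fold. Values did not overlap for 26.3% of genes, against 2.86% by chance.

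Further rises were those of Sectm1b (3.23 ± 0.233), the Ras-association gene Rassf4 (3.20 ± 0.134) and Ifit1, an interferon-induced gene (3.10 ± 0.949, adjusted p = 0.0246, and between 0.00275 and 0.0675 over the alternatives). Ifit1 varied between rats, from 4.02 to 9.59 in phase 3, and its phase 2 level of 3.63 was near the 3.59 of the olfactory receptor genes, so the size of its change is not exact. Its call ended with an intensity trend and robust prior (0.0675) and without phase 3 rat 2 or 4 or phase 2 rat 1, 2 or 4, at adjusted p between 0.0513 and 0.0613. Further falls were those of Nnat (-3.58 ± 0.275), Ankef1 (-3.25 ± 0.336), the adipocyte galectin gene Lgals12 (-3.09 ± 0.333) and Acvr1c (-2.99 ± 0.284).

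The adipocyte markers had a median change of -1.81 (camera adjusted p = 2.53e-11, and adjusted p = 0.132 with an estimated correlation), with Cidec at -1.81, Aqp7 at -2.89, Lep at -2.28 ± 0.308 and Adipoq at -1.46 ± 0.169. Adipokines fell in 9 of 13 cases and rose in 2 (camera adjusted p = 0.000146, and adjusted p = 0.132 with an estimated correlation), with the retinol-binding protein gene Rbp4 at -2.35. Lipolysis and droplet genes fell in 9 of 14 and rose in 1 (camera adjusted p = 6.84e-05, and adjusted p = 0.132 with an estimated correlation), with G0s2 at -2.77, the monoglyceride lipase Mgll at -1.16, Lipe at -1.05 ± 0.132 and Pnpla2 at -0.49 ± 0.0897. Lpl fell by 0.25 ± 0.0777 (adjusted p = 0.0286, and between 0.00525 and 0.14 over the alternatives), a call that ended with centred arrays (0.14), with quantile normalisation (0.0501), with a fit of only these groups (0.0747) and when phase 2 rat 1, 2 or 3 or phase 3 rat 2, 3 or 4 was left out, at adjusted p between 0.0526 and 0.0851. Triglyceride synthesis genes fell in 7 of 12 and rose in 1 (camera adjusted p = 0.00029, and adjusted p = 0.168 with an estimated correlation), with Pck1 at -2.49 ± 0.309, Gpat3 at -1.60 and Dgat1 at -1.53. Over some of these lists phase 3 rat 1 lay nearer the fed rats than the other phase 3 rats did, with a mean over the adipocyte markers of -1.24 relative to fed where the others lay between -2.344 and -1.951, and over the lipolysis list of -0.3783 where they lay between -0.8764 and -0.7483. Of adipogenic transcription factors 8 of 17 fell and 4 rose, with Cebpa at -1.17 and Cebpd at 1.15.

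Of the fatty acid uptake genes 6 of 11 fell and none rose (camera adjusted p = 0.000491, and adjusted p = 0.132 with an estimated correlation), with Acsl1 at -1.79 and Fabp4 at -0.48. Fatty acid oxidation genes fell in 9 of 19 and rose in 1 (camera adjusted p = 0.00318, and adjusted p = 0.52 with an estimated correlation), with Acaa2 at -1.09. Cpt1a differed by 0.10 ± 0.103 and did not pass (adjusted p = 0.505). Of the PPAR targets 4 of 15 rose and 4 fell, with Pdk4 at 2.06 ± 0.173 and Bdh1 at 0.81. Glycolysis genes fell in 8 of 21 (camera adjusted p = 0.00888, and adjusted p = 0.439 with an estimated correlation), citric acid cycle genes in 8 of 16 (camera adjusted p = 0.00418, and adjusted p = 0.52 with an estimated correlation) and respiratory chain genes in 13 of 25, with 1 rising (camera adjusted p = 3.58e-05, and adjusted p = 0.505 with an estimated correlation). Ldha was at -1.05, Pc at -1.89 and Ndufb5 at -0.68. De novo lipogenesis genes rose in 5 of 15 cases and fell in 5, with Fasn at -0.95 ± 0.162 and Scd2 at 1.17. Of 20 cholesterol synthesis genes 4 rose and 1 fell, with Insig1, the sterol sensor of the pathway, at 0.88 and Fdps at 0.49. The rise of Sqle lost its call in a fit of only these groups (limma adjusted p = 0.0685). It also did so without phase 2 rat 1, 2 or 4 or phase 3 rat 2, 3 or 4 (between 0.0518 and 0.0857). Thermogenic genes had a median of 0.0123 (camera adjusted p = 0.417), and the fall of Ppargc1b lost its call in several alternatives.

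FOXO and atrophy-associated genes rose in 15 of 18 cases and none fell (camera adjusted p = 2.32e-09, and adjusted p = 0.0293 with an estimated correlation), with Fbxo30 at 1.17 and Fbxo32 at 1.22 ± 0.12. Proteasome subunits, which had fallen in phase 2, rose in 12 of 32 cases and fell in 1 (camera adjusted p = 0.000995, and adjusted p = 0.519 with an estimated correlation), with Psma6 at 0.90 and Psmd8 at 0.77 (0.78 and 0.42 as the mean of their probe sets, of which the dimmer did not pass), while the immune-type activator subunit gene Psme2 was at -0.64. Autophagy and lysosome genes rose in 9 of 30 and fell in 3 (camera adjusted p = 0.00888, and adjusted p = 0.432 with an estimated correlation), with Ctsl at 1.24. Glucocorticoid-induced genes rose in 14 of 19 and fell in 2, and 17 rose adjusted over the list alone (camera adjusted p = 4.87e-06, and adjusted p = 0.257 with an estimated correlation), with the metallothionein genes Mt1 at 3.08 and Mt2A at 2.25. Circadian clock genes rose in 8 of 15 and fell in 1 (camera adjusted p = 0.00236, and adjusted p = 0.132 with an estimated correlation), with Nr1d1 at 1.21. In the ER stress and amino acid response 6 of 21 rose and 5 fell, with Atf4 at 1.12, Dnajb9 at 1.17 and Asns at -1.73. Amino acid catabolism genes rose in 4 of 22 and fell in 6. Antioxidant genes rose in 7 of 23 and fell in 7, with Gstm1 at 2.03, Sod3 at -2.59 and catalase, Cat, at -1.38. In insulin signalling 9 of 18 rose and 4 fell, with Igfbp3 at 1.97 and Igf1 at -1.15.

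Matrix genes fell in 19 of 22 cases and none rose, with a median of -1.03 (camera adjusted p = 8.43e-13, and adjusted p = 0.132 with an estimated correlation), with Fbn1 at -1.95, Loxl2 at -1.92 and Serpinh1 at -1.35. Fibroblast and progenitor markers fell in 9 of 13 and rose in 1 (camera adjusted p = 1.6e-06, and adjusted p = 0.132 with an estimated correlation), with Col14a1 at -1.50 and Pi16 at -1.77. Mesothelial markers fell in 6 of 11 (camera adjusted p = 0.00841, and adjusted p = 0.437 with an estimated correlation), and Schwann cell and nerve markers in 4 of 7 (camera adjusted p = 0.00917, and adjusted p = 0.132 with an estimated correlation), with S100b at -1.68. Of 31 cell cycle genes 4 fell and 2 rose (camera adjusted p = 0.0516, and between 0.00201 and 0.719 over the alternatives, of which 11 passed). Of 14 endothelial markers 2 fell and 1 rose, and of 10 smooth muscle markers 1 rose, Myocd, by 0.64.

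Among blood cell genes, T and NK cell markers fell in 7 of 17 cases (camera adjusted p = 0.00841, and adjusted p = 0.257 with an estimated correlation), with Cd3g at -1.02, and erythroid markers in 4 of 6 (camera adjusted p = 0.00841, and adjusted p = 0.244 with an estimated correlation), with the haem synthesis gene Alas2 at -2.15. Inflammatory mediators rose in 8 of 25 and fell in 1 (camera adjusted p = 0.0454, and adjusted p = 0.52 with an estimated correlation), among them Orm1, whose phase 2 level of 3.65 was near background, with Hp at 1.48 and the adhesion molecule gene Vcam1 at -1.20. B cell markers had a median of -0.225 (camera adjusted p = 0.0564, and 0.0224 without phase 2 rat 4) and mast cell markers one of -0.174 (camera adjusted p = 0.139). The fall of Ms4a1 lost its call without phase 2 rat 1 or 3. That of Cpa3 did so without phase 2 rat 2 or phase 3 rat 3 or 4. Macrophage markers rose in 4 of 19 and fell in 3, with Lgals3 at 1.20, the lysosomal Cd68 at 1.08 and Adgre1 at -0.9966. Neutrophil markers rose in 4 of 11 and fell in 1. Of these, S100a8 lay at 3.53 in phase 2 rats, near background, and between 4.14 and 6.89 in phase 3 rats, so the size of its rise is not exact. The interferon response list was split, with 3 of 26 rising and 4 falling (camera adjusted p = 0.441), and it passed as lower without phase 3 rat 2 (adjusted p = 0.000275, between 0.000275 and 0.913 over the alternatives). Hepatocyte markers rose in 1 and fell in 1 of 14, where the rise, Apoc3 (0.64), ended without phase 2 rat 1 or phase 3 rat 4 (adjusted p of 0.0594 and 0.0627), and skeletal muscle markers rose in 1 and fell in 1 of 11.

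With an estimated correlation only the FOXO and atrophy-associated list kept its call among the 21 called in phase 3 against phase 2. The call of inflammatory mediators ended with centred arrays, without the dimmest 40% of genes and without phase 2 rat 1 or 4 or phase 3 rat 2 or 3 (adjusted p between 0.0586 and 0.136 there, and between 0.00573 and 0.136 over all alternatives), and without the dimmest genes so did those of T and NK cell markers (adjusted p = 0.308, between 0.00222 and 0.308) and glycolysis (adjusted p = 0.0744, between 0.00392 and 0.0744).

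The course of single genes over the phases was compared last. Of the genes changed in phase 2, 2973 changed in the same direction in phase 3 against fed (1045 higher and 1928 lower), which was 81.5% of the phase 2 calls, and 52 changed in the other direction. Both comparisons use the same fed rats. Independent lists of these sizes would share 296 higher and 546 lower genes. In 50 simulations of unchanged groups against shared controls at most 0 genes were shared, but such groups hardly give calls, so that count is no test of the overlap. Across genes, which are not independent replicates, the changes correlated at 0.769, where shared controls alone gave 0.498, and the covariance was 0.2 against 0.00903. With separate pairs of fed rats for each comparison, 1802 to 2063 genes were shared and the correlation was 0.714 to 0.741.

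A smaller set of genes turned back between the phases. Of the genes changed in phase 2 against fed, 231 rose and then fell in phase 3 against phase 2, and 190 fell and then rose. Independent lists would share 212 and 287, which together is more than the 421 found, and the 50 simulations gave at most 0 for the reason above. With separate pairs of phase 2 rats 165 to 211 genes turned back in all. Another 1255 genes changed in the same direction in both steps. The correlation of the changes was 0.232 where a shared group alone gave -0.504, and the covariance was 0.0396 against -0.00917. Of the genes that turned back, 31 that had risen ended below the fed level and 21 that had fallen ended above it, each past the threshold in all 3 comparisons. Pck1, Acvr1c and the endothelial gene Eng (0.64, then -1.04) were among the former, and Rassf4 (-0.46, then 3.20) and Gstm1 (-0.44, then 2.03) among the latter.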

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

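The tests of other cell types' markers, hepatocyte, skeletal muscle and smooth muscle minus endothelial markers were chosen only after the results they weigh had been seen. The comparison with random lists was added after the data and the pattern had been seen, with its bound written before its own result, and the splits of the arrays were set before. Bootstrap intervals here and below resample the genes of a list, not the rats, so they do not measure the spread between rats.

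The splits argue against chance as the source of the gene counts: the real grouping was the only 1 of the 35 splits of each comparison's 8 arrays to give as many genes. A share of 1 in 35 is the smallest that such splits can give, so it does not exclude chance. Phase 2 against fed gave 1401 higher and 2248 lower genes and no other split more than 5, phase 3 against fed gave 3066 and 3523 and phase 3 against phase 2 gave 1853 and 2193, where the highest other split gave 0. The overlaps of 2973 and 421 genes were each reached by 1 of 100 drawn splits of the 12 arrays, the real one, and the highest other gave 0, but other splits give almost no calls that could overlap, so these counts say nothing about chance in the overlaps. For the numbers of gene lists called by camera at its preset correlation, these splits cannot decide on chance. As many lists were called in 10, 3 and 4 of the 35 splits, with 16, 19 and 21 lists in the real grouping and up to 19, 21 and 22 in others. Each other split that reached the real count kept 3 rats of a group together, so it still held part of the real difference. Splits that mixed the groups evenly gave up to 10, 11 and 10 lists.

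Adipocyte markers, fibroblast markers and matrix genes were lower in phase 3 than in phase 2. A smaller share of adipocyte RNA would raise the markers of all other cells. Of 107 markers of 9 other cell types, outside these lists, 10 rose and 27 fell, with a median of -0.179 (95% bootstrap interval -0.231 to -0.0838). With centred arrays the interval, -0.141 to 0.00627, reached 0. Many of these markers were dim and could hardly show a rise. Of the B cell markers 0 of 8 lay above the fed median of all genes, and of the T and NK cell markers 2 of 17. The brighter endothelial and macrophage markers had medians of -0.101 and -0.179. Markers of the other cells thus did not rise as a set. A smaller share of adipocyte RNA, or a loss of adipocytes and fibroblasts together, cannot be excluded by this, as the shares of other cells can change too. The narrower range of values on phase 3 arrays would lower bright genes of any kind, but the pooled median of the 48 genes was -1.09. All 10000 random lists of the same levels lay between -0.286 and 0.251. A lower expression per cell in phase 3 stays open, as it was not tested.

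Cyp2e1, Gulo and Slc27a2, genes the liver is known for, were among the largest rises in phase 2, and the extraction protocol speaks of liver. Liver RNA in the samples would bring all abundant liver transcripts, but the 14 hepatocyte markers had a median change of -0.0116 (95% bootstrap interval -0.0392 to 0.119), and in phase 2 Ttr stood at 3.938, Fga at 3.581 and Apoa1 at 5.762 on the log2 scale, low for abundant liver transcripts. Alb went the way liver RNA would take it, from 8.327 to 9.622, a change of 1.295 ± 0.598 that did not pass (adjusted p = 0.139) and was smaller than the 6.347 of Cyp2e1. Of the 14 markers 2 lay above the fed median of all genes, and 0 stood in another list. Which cells of the pad express the genes was not tested.

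Smooth muscle markers were higher in phase 2 and phase 3 than in fed rats. A larger share of all vessel cells would raise endothelial markers alike, but the smooth muscle median exceeded the endothelial one by 0.748 (95% bootstrap interval 0.237 to 1.09) in phase 2 and by 0.796 (0.184 to 1.24) in phase 3. Relative to fed, the smooth muscle list mean was 0.7487 to 1.603 in phase 2 rats and 0.6213 to 1.267 in phase 3 rats. Fed rats lay between -0.2764 and 0.341 on it. The endothelial list mean was 0.2796 to 0.5093 in phase 2 rats and 0.2013 to 0.3463 in phase 3 rats. Skeletal muscle cut with the pad is argued against by a median of 0.0302 for its markers (-0.106 to 0.0649) in phase 2. In phase 3 against fed their median was 0.0934, and with centred arrays 4 of the 11 rose and 1 fell. No interval was made for phase 3, so skeletal muscle was not excluded there. A larger share of smooth muscle cells alone or a higher expression in them could each give the pattern. Markers of epididymis and testis, the organs beside the pad, changed by at most 0.203 in phase 2, which argues against their tissue there. In phase 3 some of these 13 markers rose, as given above, with a list median of 0.157 against fed. That median lay inside the 95% range of random lists of the same levels, -0.00796 to 0.202. Of the 13 markers 0 lay above the fed median of all genes, so all were dim. Tissue of epididymis or testis was not excluded in that phase. Muscle of other organs was not tested.

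In 28 of 636 groups of 4 rats a named gene had a rat whose gap to the nearest other made up a larger share of the group's range than Dixon's critical value, and chance gives about 1 in 20, or 31.8. Phase 3 rat 1 held 8 of them, for Gpam (0.963), Dlat (0.934), Atf4 (0.902), Mt2A (0.886), Mt1 (0.878), Pde3b (0.874), Dnajb9 (0.86) and Rxrg (0.838). Phase 3 rat 2 held those of Psmb10 (0.974), Stat2 (0.941), Cd4 (0.919) and Aif1 (0.863), each with a level above the other phase 3 rats. Phase 3 rat 3 held those of Gpt2 (0.85) and Lcn8 (0.833), and its upper quartile over all probe sets, 7.8287, lay below the 7.95 to 7.9592 of the others (0.93).

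Fed rat 4 held those of Ifit1 (0.946), Mt1 (0.914), Ndufb5 (0.901) and Psmb5 (0.853), and its Ifit1 level was 7.0491 where the other fed rats lay between 3.5317 and 3.7231. Fed rat 2 held those of Scd2 (0.938), Angptl4 (0.916) and Plin2 (0.91), and fed rat 3 those of Nampt (0.934) and Dgat1 (0.878). Among phase 2 rats they were Pde3b (0.926) and Cdh19 (0.851) in rat 1, Cpa3 (0.946) in rat 2, Dpp4 (0.885) in rat 3 and Lcn8 (0.84) in rat 4.

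For 5 named genes phase 2 and phase 3 moved to opposite sides of the fed level, and the difference between the phases was tested in the model. It was 2.03 for Gstm1, -2.49 for Pck1, -2.99 for Acvr1c, 3.2 for Rassf4 and -1.04 for Eng. Of the 13582 probe sets without a gene name in the annotation, which entered no comparison above, 734 were higher in phase 2 and 2131 in phase 3 than in fed rats, and 888 and 1524 lower.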

How the results depend on the processing

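Cyclic loess normalisation, the matched random lists and the test of olfactory receptor genes were chosen after the data had been seen, the last of these before its own result. Most named genes were chosen as the strongest of the main fit, so their stability follows partly from that choice. Over all genes 77.3% of the phase 2 against fed calls were kept without fed rat 4. The test of every probe set and the minimum change were not run for named genes. Without the dimmest 40% of genes 327 of their results could be compared. Of 362 results for named genes, 336 kept their direction and their side of the threshold under every alternative in which they were compared. Of their 7567 alternative values 136 no longer passed, mostly with fewer rats, and 4 reversed, none of them past the threshold: Adipoq in phase 2 against fed with centred arrays (0.004863), Lpl in phase 2 against fed with cyclic loess (-0.02546), and Pnpla2 in phase 3 against fed with cyclic loess (-0.0003205) and without phase 3 replicate 1 (-0.05421, the lowest of -0.05421 to 0.09646 without 1 rat), and the cause was not tested. Centring each array raised the genes higher in phase 3 to 6115 against fed and 3115 against phase 2, since it adds back the lower medians of those arrays. Testing every probe set gave 5222 higher in phase 3 against fed, with more features tested. A minimum change of 1 log2 unit left 167 higher and 265 lower genes in phase 2 against fed, 472 and 907 in phase 3 against fed, 210 and 312 in phase 3 against phase 2, and overlaps of 362 and 28, by its construction. An estimated correlation left 3, 1 and 1 lists called, and fry, which does not compare a list with other genes, called 25 in phase 2 against fed.

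Leaving out 1 rat at a time gave 1001 to 1664 higher and 1828 to 2470 lower genes in phase 2 against fed, 2661 to 3175 and 3240 to 3501 in phase 3 against fed, and 1432 to 1946 and 1872 to 2190 in phase 3 against phase 2. It gave 14 to 18, 17 to 19 and 21 to 23 lists, and overlaps of 2365 to 3308 and 301 to 518. The highest counts in phase 2 against fed, 1664 and 2470, came without phase 3 rat 3, which entered that comparison only through the shared spread. A fit of only the 2 groups compared called 4354, 6173 and 3404 genes in the 3 comparisons, where the shared fit called 3649, 6589 and 4046. Whether the first or the last comparison held more calls thus depended on the fit. Rats with the same replicate number did not resemble each other (residual correlations of -0.155 to 0.188 in 12 pairs), and the replicate number as a block gave 1361 and 2178, 3053 and 3473, and 1829 and 2166 genes. Of the called lists, 16 of 16, 18 of 19 and 20 of 21 lay outside the 95% range of matched random lists, endothelial markers in phase 3 against fed and glycolysis in phase 3 against phase 2 excepted. Random lists hold unrelated genes and so leave out the correlation within a list, as the preset correlation nearly does, which makes this no separate support. Some lists that were not called also lay outside, such as triglyceride synthesis in phase 2 against fed. Signal over background limits small changes of dim genes. The 1105 olfactory receptor genes were taken as mostly silent in fat. Their median change in phase 3 against fed was 0.0939 (95% bootstrap interval 0.085 to 0.1), which reaches the bound of 0.1 set beforehand. It was 0.0286 with quantile normalisation, 0.025 with cyclic loess and 0.249 with centred arrays, so it depends on the scaling, and camera called these genes higher (adjusted p = 0.012, and adjusted p = 0.632 with an estimated correlation). A raised background on phase 3 arrays and a change of dim genes therefore cannot be told apart. Without the dimmest 40% of genes 2474 were higher and 3185 lower.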

Other observations

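The gene families below are 4 of 12 that were tested, and they were chosen after counts for them had been seen, and the test of imprinted genes was chosen after Mest, Nnat and Zim1 had been seen, with its bound set before its result.

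Genes of the ribosome moved apart by compartment. Of 71 cytosolic ribosomal protein genes 31 rose and 1 fell in phase 2 against fed (median 0.208, camera adjusted p = 2.07e-09, and adjusted p = 0.414 with an estimated correlation), and 31 rose and 2 fell in phase 3 against fed (median 0.186, camera adjusted p = 0.000885, and adjusted p = 0.632 with an estimated correlation). Of 68 mitochondrial ribosomal protein genes 39 fell and 1 rose in phase 2 (median -0.318, camera adjusted p = 1.17e-11, and adjusted p = 0.334 with an estimated correlation), and 43 fell and 3 rose in phase 3 (median -0.411, camera adjusted p = 1.93e-09, and adjusted p = 0.606 with an estimated correlation). Of 44 translation initiation factors 20 rose and 1 fell in phase 3 against phase 2 (median 0.231, camera adjusted p = 8.72e-05, and adjusted p = 0.307 with an estimated correlation). Of 19 tubulin genes 11 fell and 2 rose in phase 2 against fed (median -0.446, camera adjusted p = 0.00145, and adjusted p = 0.334 with an estimated correlation). These directions held under each scaling.

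The genes that turned back between the phases were tested for the 41 lists against all genes called in the same direction in phase 2, with a one-sided Fisher's exact test. Of 62 tests 0 passed after adjustment and 7 had an unadjusted p below 0.05. Among them, 4 of the 6 PPAR targets that rose in phase 2 fell in phase 3 against phase 2 (one-sided exact p = 0.00822, adjusted p = 0.303), and 5 of the 22 proteasome genes that fell in phase 2 rose again (one-sided exact p = 0.0329, adjusted p = 0.303).

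Of the imprinted genes, Mest and Nnat were among the largest falls and Zim1 rose by 2.62 in phase 2 against fed, and imprinted genes were hypothesised to change more than others. The other 26 had a median absolute change of 0.374 in phase 3 against fed, at percentile 93.08 of random lists of the same levels, below the 95th percentile of 0.388, so the bound set beforehand was not met. Among them 9 fell, such as H19 (-2.25), named after its value was seen, and 5 rose.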
